A study of Rattus norvegicus with 15 samples.

How the data were processed

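RNA of right lungs of rats given a vehicle, SWCNT or MWCNT was hybridised by the authors to 1-colour Agilent whole rat genome arrays. The design has 15 groups of 4 arrays, and per the labels each group is 4 rats. The files tie no array to an animal, so the p-values measure the spread between these arrays, which may be technical in part. Per the file headers, Agilent Feature Extraction 10.7.3.1 gave, for each of 45018 spots, a spot intensity, a local background intensity and a processed intensity that is background-subtracted and detrended within the array. Flags in the other columns are 0 or 1 per the file headers and mark spots well above background, saturated or uneven.

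The deposited value tables hold log2 values. By comparison with the scanner intensities, they are the log2 processed intensity shifted by the 75th percentile of the array and centred per probe on the median of the control arrays of the same day. In 14 of 15 groups the series table is the mean of the 4 arrays, so its values run in the direction nanotube minus control. Its medians per group, in the order control, SWCNT and MWCNT, were 0.000952, 0.0113 and 0.043 at day 1, 0.000352, -0.088 and 0.0926 at day 3, -0.00175, -0.0548 and 0.0422 at day 7, 0.000781, 0.0984 and 0.0387 at day 30, and -2e-04, 0.0665 and -0.136 at day 90. One deposited per-array value file, that of SWCNT day 1 array 3, repeats the values of control day 1 array 3 and was left out wherever deposited values were used.

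All fits reported here start from the scanner intensities. The 1639 control spots were removed, which left 43379 spots for 41012 probes, and replicate spots were averaged. The log2 processed intensity was shifted by the 75th percentile of each array. Probes were kept if they were well above background on all 4 arrays of at least 1 group, which left 29497. Gene names came from the annotation by accession for 17783 probes, by symbol for 2957 and by synonym for 542, and 19730 kept the name in the files. The probe with the highest mean stood for each of 24650 names. Probe positions are those the files give on the rn4 build.

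Linear models with a mean for each of the 15 groups were fitted with limma 3.58.1 (lmFit, then eBayes with an intensity trend, prior degrees of freedom 5.77) in R 4.3.3 with the package data.table (version 1.17.8). P-values were adjusted by Benjamini and Hochberg within a comparison, and called genes passed 0.05 with at least a 2-fold change. Each nanotube was compared with the control of its day, and MWCNT with SWCNT. The change of each effect from day 1 to day 90 was tested as a difference of differences, and the controls of these days were compared. Camera tested 34 gene lists, fixed by name before their values were seen, with a preset correlation of 0.01, and again with an estimated correlation. Its p-values were adjusted over lists and comparisons. The lists had 407 members, of which 370 were on the array. Comparisons, lists, thresholds and the rule for naming genes were fixed before the data were examined.

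The rule named, for each comparison, the 5 highest and 5 lowest genes past both thresholds whose 4 arrays of 1 group all lay above the 4 of the other, with a symbol that is not a placeholder. It added the 10 genes with the highest mean change among those higher at all 5 days in both materials, and the 10 lowest among those lower at all 5 days in either. For the changes between days the overlap condition was dropped. List members with the largest changes, and some that did not pass, were named as well. For the comparisons of slides the 10 highest and 10 lowest genes past both thresholds were drawn on, a choice made after the values were seen, as were the genes of the plots.

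Each group lay on a slide of its own, so slide and group cannot be told apart within a day. Scan days were shared by MWCNT day 7 and control day 30, by SWCNT and MWCNT at day 30, and by SWCNT and MWCNT at day 90. Hence the comparisons of materials at days 30 and 90 lie within a scan day, and every other comparison of a day spans 2. A comparison of slide means over days 3 to 90, with 4 slides per material, was added after seeing the data, as were the change from day 3 to day 90 and the later controls as reference for day 1.

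The alternatives tried were quantile normalization, normexp background correction with an offset of 50, no filter on dim probes, probes above background on at least 50% of all arrays, the mean of all probes of a gene and the authors' per-array values. Others were eBayes without a trend, fits of only the groups compared, controls of all 5 days, fry for the lists, day as a block or all 5 days for the slides, and leaving out each array in turn. Random draws used seed 1. No paired analysis was possible because no label links animals of different groups.

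The fit was tested on simulated data with 24650 genes in the layout of SWCNT against control at day 90. Of genes changed by 1.5 (log2), 94% were called, and of those changed by 3, 100% were called, with 1 false call among 24400 unchanged genes. With slide means as units, 95% of genes changed by 1.5 were called, with 2 false calls. When slide effects of the size seen between control slides were added to 2 unchanged groups, the fit of arrays made 658 false calls.

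The median standard deviation between arrays of a group ran from 0.102 to 0.236 (log2). The lowest correlation across genes of 2 arrays of 1 group was 0.976, and the highest of any 2 arrays 0.996. The median standard deviation between control slides of days 3 to 90 was 0.131, against 0.0938 expected from a spread of 0.188 between arrays. The first and the second principal component held 43.7% and 21.1% of the variance.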

Results

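Gene expression was measured in right lungs of male Wistar rats given 1 intratracheal dose of single-walled (SWCNT) or multi-walled (MWCNT) carbon nanotubes, which are rolled sheets of carbon, or of the vehicle. Per the labels, a dose was 0.32 mg in 0.4 mL of bovine serum albumin at 10 mg/mL, and lungs were taken after 1, 3, 7, 30 or 90 days. Each of the 15 groups (control, SWCNT and MWCNT at 5 days) had 4 rats and 4 one-colour Agilent arrays, 60 arrays in all. The 75th percentile of intensity ran from 637 to 1557 per array, 56.4% to 78.6% of spots were well above background and 0 spots were saturated, and the number of arrays limits the precision. After removal of dim probes, 24650 gene names were tested, 13000 of them with a symbol. The title of the series gives lung expression after the 2 materials as its subject, and each comparison asks how expression differed between groups of 1 day.

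Changes are log2 fold changes with the standard error (SE) of the fit, n = 4 arrays per group, and adjusted p from limma. Genes called had adjusted p under 0.05 and at least a 2-fold change. List members counted as up or down had adjusted p under 0.05 at any fold, and list medians are medians of log2 fold changes. A gene well above background on an array is called detected there. For a gene detected on 0 of 4 arrays of a group, the fold is a lower bound, and a list median with such members at their bounds is given where it differs by over 0.1. The bound compares the mean of the brighter group with the mean of the dim group after each array is raised to its lowest signal among probes well above background. Each group had its own slide, so the 2 cannot be told apart within a day. Pairs of control slides of days 3 to 90 differed at 219 to 875 genes by the same rule. The day 1 control differed from these at 4312 to 5776, so day 1 follows the later days. Only the later controls are titled (#2), unexplained.

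At day 3, chemokine and acute phase transcripts were higher in SWCNT lungs. Spp1, which encodes osteopontin (NM_012881, probe on chromosome 14 from 6422382 to 6422441 of the rn4 build), rose by 6.30 (SE 0.55, adjusted p = 4.93e-13, mean 3.49 against -2.81). The other largest increases were Orm1 (at least 24.9-fold higher, adjusted p = 3.31e-13), Slc26a4 (5.05, SE 0.29, adjusted p = 2.05e-19), Mmp7 (4.94, SE 0.53, adjusted p = 3.14e-10, detected on 1 of 4 control arrays) and Retnla (4.94, SE 0.45, adjusted p = 1.85e-12), which encode an acute phase protein, an anion exchanger, the protease matrilysin and a resistin-like protein. Among CC chemokines, which attract leukocytes, 9 of 13 rose and 0 fell (9 and 0 adjusted over the list alone, median 1.40, adjusted p = 9.5e-09). Ccl12 (4.20), Ccl22 (4.02) and Ccl2 (3.37) were highest. Among interferon-inducible genes 13 of 16 rose and 0 fell (15 and 0 adjusted over the list alone, median 1.13, adjusted p = 1.35e-10, adjusted p = 0.104 with an estimated correlation). Gbp2 (0.33, adjusted p = 0.0699) did not pass. Of acute phase genes 10 of 11 rose and 0 fell (11 and 0 adjusted over the list alone, median 0.79, adjusted p = 4.86e-13). Of cell cycle genes 21 of 23 rose and 0 fell (22 and 0 adjusted over the list alone, median 1.21, adjusted p = 2.24e-13, adjusted p = 0.111 with an estimated correlation). Neutrophil markers moved less evenly, with 6 of 9 up and 0 down (6 and 0 adjusted over the list alone, median 1.48, adjusted p = 5.57e-05), led by S100a9 (2.79) and S100a8 (2.10). Cholesterol synthesis genes also moved up, with 11 of 13 up and 0 down (11 and 0 adjusted over the list alone, median 0.67, adjusted p = 2.38e-07, adjusted p = 0.0989 with an estimated correlation).

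The lowest named genes at day 3 were dim in SWCNT lungs, namely Or2y1d (at least 4.55-fold lower, adjusted p = 7.58e-14), Stfa3 (at least 2.36-fold lower, adjusted p = 1.34e-05), Palld (at least 2.13-fold lower, adjusted p = 1.76e-07), Nppb (at least 1.55-fold lower, adjusted p = 0.00722) and Zfp804a (at least 2.48-fold lower, adjusted p = 5.65e-09). Of endothelial markers 0 of 12 rose and 6 fell (0 and 6 adjusted over the list alone, median -0.34, adjusted p = 0.0251, adjusted p = 0.379 with an estimated correlation). Alveolar type 2 markers moved the other way, with 9 of 12 up and 1 down (10 and 1 adjusted over the list alone, median 0.45, adjusted p = 2.82e-05, adjusted p = 0.0538 with an estimated correlation), although their lipid desaturase Scd fell by 1.83. Of 24650 genes, 530 rose and 724 fell by at least 2-fold, 624 of them detected on all 8 arrays. Of those, 341 rose and 283 fell. Quantile normalization turned the balance, with 560 higher and 456 lower, as did normexp background with 250 and 100.

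At day 7, SWCNT lungs showed a broad rise of chemokine and interferon-inducible transcripts. Spp1 (8.43, SE 0.55, adjusted p = 4.68e-18) and Mmp7 (7.99, SE 0.53, adjusted p = 1.37e-17, detected on 2 of 4 control arrays) had the largest values, followed by the interferon-induced chemokine Cxcl11 (NM_182952, probe on chromosome 14 from 17252192 to 17252251), at least 59.4-fold higher with adjusted p = 3.05e-18, then Ccl12 (6.31, SE 0.41, adjusted p = 5.05e-18) and Mmp12 (5.74, SE 0.40, adjusted p = 4.55e-17). Of interferon-inducible genes 14 of 16 rose and 0 fell (15 and 0 adjusted over the list alone, median 2.13, adjusted p = 2.16e-14), with Cxcl10 (5.52), Ifit3 (3.27) and Mx1 (3.15) high and Irf1 (0.07, adjusted p = 0.72) not passing. CC chemokines followed, with 8 of 13 up and 0 down (8 and 0 adjusted over the list alone, median 2.26, adjusted p = 1.89e-07), including Ccl7 (4.99) and Ccl2 (4.51). Ccl5 (-0.14, adjusted p = 0.45) and Ccl11 (-0.20, adjusted p = 0.697) did not pass. Inflammatory mediators were mostly higher, with 13 of 15 up and 1 down (13 and 1 adjusted over the list alone, median 1.29 or 0.85 at bounds, adjusted p = 1.91e-08), among them Il1rn (2.46) and Il1r2 (2.74), and Nos2 (at least 5.32-fold higher, adjusted p = 5.62e-13), which makes nitric oxide, but Il33 fell by 0.66. Of T cell markers 11 of 12 rose and 0 fell (11 and 0 adjusted over the list alone, median 0.67, adjusted p = 6.07e-07). Among them were Icos (1.98) and Foxp3 (1.71, detected on 2 of 4 control arrays).

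Among cell cycle genes at day 7, 22 of 23 rose and 0 fell (22 and 0 adjusted over the list alone, median 1.76, adjusted p = 5.26e-14, adjusted p = 0.101 with an estimated correlation). Rrm2 (2.46) and Kif2c (2.33, detected on 1 of 4 control arrays) were highest. Complement genes rose as a group, with 13 of 14 up and 0 down (13 and 0 adjusted over the list alone, median 1.28, adjusted p = 3.99e-15). The largest decreases were Tac1 (-2.62, SE 0.29, adjusted p = 2.39e-10), Inmt (-2.23, SE 0.26, adjusted p = 5.02e-10) and Serpinb10 (-2.18, SE 0.26, adjusted p = 1.73e-09), then Kcnmb2 (-1.95) and Fmo2 (-1.90). Tac1 encodes the precursor of substance P, and Inmt and Fmo2 encode a methyltransferase and a monooxygenase. Of endothelial markers 0 of 12 rose and 11 fell (0 and 12 adjusted over the list alone, median -0.77, adjusted p = 6.44e-07). Cdh5 (-1.08) and Sox18 (-1.02) were lowest. Of alveolar type 1 markers 0 of 9 rose and 8 fell (0 and 9 adjusted over the list alone, median -0.56, adjusted p = 0.000177, adjusted p = 0.115 with an estimated correlation). Cav2 (-0.96) was lowest. Altogether 1115 genes rose and 366 fell, 922 of them detected on all 8 arrays.

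At day 30, lysosome and particle-handling genes stood high in SWCNT lungs. The largest increases were Mmp7 (at least 438-fold higher, adjusted p = 1.95e-20), Spp1 (9.20, SE 0.55, adjusted p = 4.11e-20) and Mmp12 (7.19, SE 0.40, adjusted p = 3.34e-21), then Atp6v0d2 (6.61) and Retnla (6.43). Mmp12 (NM_053963, probe on chromosome 8 from 4259057 to 4259413) encodes macrophage elastase, and Atp6v0d2 (NM_001011972, probe on chromosome 5 from 34476269 to 34476328) a subunit of the proton pump that acidifies lysosomes. Of lysosome genes 20 of 20 rose and 0 fell (20 and 0 adjusted over the list alone, median 1.45, adjusted p = 1.51e-20). Ctsk (5.28), Ctsz (2.18) and Ctss (2.05) were high. Of particle- and lipid-handling macrophage genes 15 of 16 rose and 1 fell (15 and 1 adjusted over the list alone, median 2.02, adjusted p = 4.51e-14). Gpnmb (3.72), Trem2 (3.65) and Cd68 (3.11) were high, while the chitinase gene Chit1 fell by 0.83. Matrix proteases and their inhibitors moved up, with 10 of 13 up and 2 down (10 and 2 adjusted over the list alone, median 0.97, adjusted p = 3.93e-05). Timp3 fell by 0.55. Of MHC class II genes 7 of 7 rose and 0 fell (7 and 0 adjusted over the list alone, median 0.90, adjusted p = 4.39e-06, adjusted p = 0.0798 with an estimated correlation). Of alternative activation genes 6 of 10 rose and 2 fell (6 and 2 adjusted over the list alone, median 0.83, adjusted p = 0.00233, adjusted p = 0.0986 with an estimated correlation). Il4r fell by 0.75.

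The largest decreases at day 30 were Spetex2f (at least 2.09-fold lower, adjusted p = 6.03e-06), Acoxl (-2.65, detected on 1 of 4 SWCNT arrays), Klk6 (-2.54), Gnai1 (at least 1.89-fold lower, adjusted p = 3.7e-08) and Prl8a9 (at least 2.59-fold lower, adjusted p = 1.34e-05). Cardiac muscle markers, expressed in rodent lung by the walls of veins, fell, with 0 of 7 up and 6 down (0 and 6 adjusted over the list alone, median -1.29, adjusted p = 0.00095, adjusted p = 0.309 with an estimated correlation). Nppa (-0.95, adjusted p = 0.337) did not pass. Of smooth muscle markers 0 of 5 rose and 5 fell (0 and 5 adjusted over the list alone, median -0.81, adjusted p = 0.00173, adjusted p = 0.176 with an estimated correlation). Of ciliated cell markers 0 of 9 rose and 9 fell (0 and 9 adjusted over the list alone, median -0.70, adjusted p = 0.000765, adjusted p = 0.142 with an estimated correlation). Of endothelial markers 0 of 12 rose and 11 fell (0 and 12 adjusted over the list alone, median -1.07, adjusted p = 3.67e-07). Among extracellular matrix genes 2 of 20 rose and 9 fell (2 and 9 adjusted over the list alone, median -0.18, adjusted p = 0.132), with Fn1 (0.75) and Tgfb1 (1.18) up and Eln (-1.04) and Postn (-0.93) down. In total 1577 genes rose and 1311 fell, 1758 of them detected on all 8 arrays.

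At day 90, the largest increases in SWCNT lungs were Spp1 (9.28, SE 0.55, adjusted p = 3.92e-20), Mmp7 (8.43, SE 0.53, adjusted p = 6.61e-19, detected on 1 of 4 control arrays) and Mmp12 (6.97, SE 0.40, adjusted p = 1.38e-20), then Retnla (6.21) and Cxcl11 (5.98, detected on 1 of 4 control arrays). Mean Spp1 was 6.48 (SD 0.52, n = 4) against -2.80 (SD 0.42, n = 4) in controls. Of lysosome genes 20 of 20 rose and 0 fell (20 and 0 adjusted over the list alone, median 1.43, adjusted p = 1.51e-20). Ctsk (5.36) was highest. Of interferon-inducible genes 14 of 16 rose and 0 fell (14 and 0 adjusted over the list alone, median 1.68, adjusted p = 1.39e-07, adjusted p = 0.2 with an estimated correlation). Chemokine transcripts were high, with 8 of 13 up and 1 down (8 and 1 adjusted over the list alone, median 1.75, adjusted p = 0.000111, adjusted p = 0.0524 with an estimated correlation) among CC chemokines, including Ccl12 (5.96) and Ccl9 (4.05). Ccl5 fell by 1.13. Of acute phase genes 11 of 11 rose and 0 fell (11 and 0 adjusted over the list alone, median 1.31, adjusted p = 1.09e-08). Of NRF2 and metallothionein genes 7 of 12 rose and 1 fell (7 and 1 adjusted over the list alone, median 0.55, adjusted p = 0.0218, adjusted p = 0.123 with an estimated correlation), with Hmox1 (2.30) and Sod2 (2.05) high and Nqo1 (0.02, adjusted p = 0.935) and Gclc (0.06, adjusted p = 0.792) not passing.

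Decreases at day 90 were led by Tac1 (-2.74, detected on 2 of 4 SWCNT arrays), Serpinb10 (-2.56), Sstr1 (-2.49), Esm1 (-2.48) and Prp15 (at least 2.59-fold lower, adjusted p = 2.35e-10). Of alveolar type 1 markers 0 of 9 rose and 9 fell (0 and 9 adjusted over the list alone, median -0.78, adjusted p = 1.94e-05, adjusted p = 0.0648 with an estimated correlation). Cav2 (-1.62) and Cav1 (-1.33) were lowest. Red cell markers fell too, with 0 of 4 up and 4 down (0 and 4 adjusted over the list alone, median -1.08, adjusted p = 0.0459, adjusted p = 0.366 with an estimated correlation). Among them were Hbb (-0.86) and Alas2 (-1.30). B and plasma cell markers were mixed, with 3 of 10 up and 5 down (3 and 5 adjusted over the list alone, median -0.32, adjusted p = 0.834), with Mzb1 (1.29) up and Cd79b (-0.74) down. At 2-fold, 1436 genes rose and 1291 fell, 1850 of them detected on all 8 arrays.

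**Figure D1:**
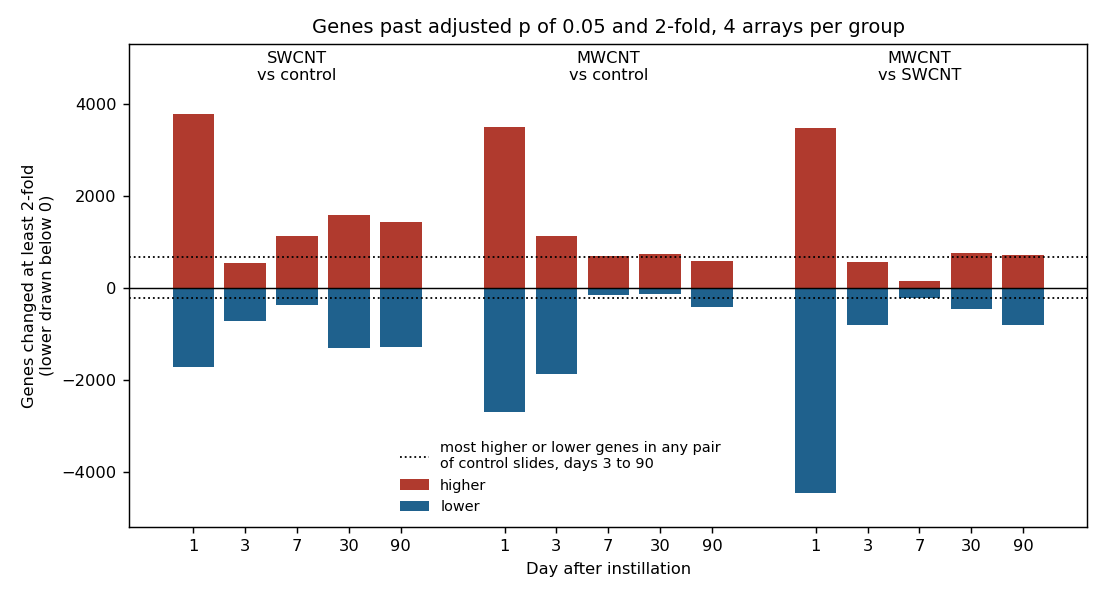
Genes changed at least 2-fold with adjusted p under 0.05 in each comparison of a day, higher above and lower below zero, with n = 4 arrays per group. Dotted lines mark the most higher or lower genes in any pair of control slides of days 3 to 90, whose totals ran from 219 to 875.

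At day 3, MWCNT lungs had the largest Spp1 change among the 5 days of this material. The largest increases were Spp1 (9.13, SE 0.55, adjusted p = 4.26e-19), Mmp7 (7.24, SE 0.53, adjusted p = 4.62e-16, detected on 1 of 4 control arrays), Il24 (6.80, SE 0.43, adjusted p = 4.39e-18, detected on 1 of 4 control arrays), Retnla (6.22) and Cxcl11 (at least 29.2-fold higher, adjusted p = 8.09e-14). Il24 (NM_133311, probe on chromosome 13 from 43831514 to 43831573) encodes a cytokine of the interleukin 10 family. Of complement genes 13 of 14 rose and 0 fell (13 and 0 adjusted over the list alone, median 1.47, adjusted p = 2.25e-11). C3 (2.02) and C3ar1 (1.97) were highest. Interferon-inducible genes rose, with 14 of 16 up and 0 down (14 and 0 adjusted over the list alone, median 1.21, adjusted p = 2.41e-06, adjusted p = 0.264 with an estimated correlation), and so did CC chemokines, with 9 of 13 up and 0 down (9 and 1 adjusted over the list alone, median 1.26, adjusted p = 9.66e-05, adjusted p = 0.0508 with an estimated correlation). Of lysosome genes 18 of 20 rose and 0 fell (19 and 0 adjusted over the list alone, median 0.99, adjusted p = 8.11e-13). Of particle- and lipid-handling macrophage genes 11 of 16 rose and 1 fell (11 and 1 adjusted over the list alone, median 0.90, adjusted p = 7.46e-07). Trem2 (2.94) and Gpnmb (2.36) were high. Mesothelium markers, which line the lung surface, were higher, with 4 of 5 up and 0 down (4 and 0 adjusted over the list alone, median 1.27, adjusted p = 0.042, adjusted p = 0.365 with an estimated correlation). Among them were Msln (1.45) and Wt1 (1.36, detected on 3 of 4 control arrays). Of neutrophil-attracting CXC chemokines 3 of 5 rose and 1 fell (3 and 1 adjusted over the list alone, median 0.96, adjusted p = 0.153). Ppbp fell by 1.06.

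The lowest named genes at day 3 were Ifna4 (-4.12, SE 0.36, adjusted p = 9.26e-14, detected on 3 of 4 MWCNT arrays), Prl8a9 (at least 3.81-fold lower, adjusted p = 1.16e-08), Or11h23b (at least 2.91-fold lower, adjusted p = 6.01e-08), Spetex2f (at least 2.61-fold lower, adjusted p = 7.5e-08) and Crisp3 (at least 2.4-fold lower, adjusted p = 1.09e-06). Of endothelial markers 0 of 12 rose and 11 fell (0 and 11 adjusted over the list alone, median -0.65, adjusted p = 8.51e-05, adjusted p = 0.101 with an estimated correlation). Cdh5 (-1.97) and Ednrb (-1.14) were lowest, while alveolar type 2 markers were higher, with 10 of 12 up and 1 down (10 and 1 adjusted over the list alone, median 0.71, adjusted p = 7.01e-05, adjusted p = 0.0671 with an estimated correlation), apart from Scd, which fell by 2.06. At 2-fold, 1125 genes rose and 1870 fell, 1447 of them detected on all 8 arrays and 1059 with 1 group below background on 4 of 4. Of the former, 813 rose and 634 fell. Quantile normalization gave 1214 higher and 1319 lower, and normexp background turned the balance to 632 and 336.

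At day 7, lysosome and MHC class II transcripts were higher in MWCNT lungs. Spp1 (7.97, SE 0.55, adjusted p = 1.07e-16), Mmp7 (6.58, SE 0.53, adjusted p = 3.91e-14, detected on 2 of 4 control arrays), Retnla (5.59, SE 0.45, adjusted p = 2.53e-14), Il24 (5.11, detected on 2 of 4 control arrays) and Atp6v0d2 (4.70) had the largest increases. Retnla (NM_053333, probe on chromosome 11 from 53206606 to 53206665) is a marker of alternatively activated macrophages. Of lysosome genes 17 of 20 rose and 0 fell (19 and 0 adjusted over the list alone, median 0.67, adjusted p = 1.05e-19). Of particle- and lipid-handling macrophage genes 13 of 16 rose and 1 fell (13 and 1 adjusted over the list alone, median 0.96, adjusted p = 2.16e-14). Of alternative activation genes 7 of 10 rose and 1 fell (8 and 1 adjusted over the list alone, median 0.56, adjusted p = 6.27e-06). MHC class II genes rose together, with 7 of 7 up and 0 down (7 and 0 adjusted over the list alone, median 0.81, adjusted p = 4.41e-10). Of cell cycle genes 22 of 23 rose and 0 fell (22 and 0 adjusted over the list alone, median 1.20, adjusted p = 2.46e-12, adjusted p = 0.129 with an estimated correlation). Few interferon-inducible genes passed, with 4 of 16 up and 0 down (5 and 0 adjusted over the list alone, median 0.27, adjusted p = 0.0225, adjusted p = 0.572 with an estimated correlation), with Cxcl11 (at least 4.02-fold higher, adjusted p = 1e-07) and Cxcl10 (2.28) high and Irf7 (0.42, adjusted p = 0.222) and Isg15 (-0.09, adjusted p = 0.839) not passing.

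Clock genes gave the lowest values of MWCNT lungs at day 7. The circadian activators Bmal1 (NM_024362, probe on chromosome 1 from 171161969 to 171162028) and Npas2 fell by 2.57 and 2.38 with adjusted p = 3.51e-25 and 5.5e-12. Their targets rose, namely Dbp (4.41), Nr1d1 (3.76) and Per2 (2.67), so that 7 of 11 rose and 3 fell (8 and 3 adjusted over the list alone, median 1.91, adjusted p = 4.95e-08) over the whole list. The other lowest genes were Spon2 (-2.31), Esm1 (-2.04) and Fam124b (-1.97, detected on 1 of 4 MWCNT arrays). Of endothelial markers 0 of 12 rose and 9 fell (0 and 9 adjusted over the list alone, median -0.48, adjusted p = 9.82e-07). Of extracellular matrix genes 7 of 20 rose and 1 fell (8 and 2 adjusted over the list alone, median 0.23, adjusted p = 0.0112, adjusted p = 0.242 with an estimated correlation), with Fn1 (0.86) and Ccn2 (0.58) up. By the 2-fold rule, 685 genes rose and 153 fell, 460 of them detected on all 8 arrays, a total inside the range of 219 to 875 for pairs of control slides.

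At day 30, complement and particle-handling genes were higher in MWCNT lungs. The largest increases were Spp1 (7.13, SE 0.55, adjusted p = 7.03e-15), Mmp7 (at least 35-fold higher, adjusted p = 8.99e-12), Retnla (5.19, SE 0.45, adjusted p = 3.29e-13) and Mmp12 (4.93, SE 0.40, adjusted p = 4.16e-14), then Atp6v0d2 (4.46). Of complement genes 13 of 14 rose and 0 fell (14 and 0 adjusted over the list alone, median 0.92, adjusted p = 1.87e-15). Of CC chemokines 10 of 13 rose and 2 fell (10 and 2 adjusted over the list alone, median 1.37, adjusted p = 2.5e-07). Ccl20 fell by 0.47. Particle- and lipid-handling macrophage genes gave 15 of 16 up and 1 down (15 and 1 adjusted over the list alone, median 1.10 or 0.89 at bounds, adjusted p = 9.03e-15). Of mast cell markers 3 of 7 rose and 0 fell (4 and 0 adjusted over the list alone, median 0.91 or 0.65 at bounds, adjusted p = 0.0227, adjusted p = 0.0591 with an estimated correlation), with Cpa3 (1.16), Cma1 (1.14) and Tpsb2 (1.10).

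The lowest values at day 30 were Bmal1 (-2.57), Npas2 (-2.44), Scd (-2.28), Spon2 (-2.16) and Fam124b (at least 3.92-fold lower, adjusted p = 1.76e-07). Clock genes gave 7 of 11 up and 3 down (7 and 3 adjusted over the list alone, median 1.81, adjusted p = 7.58e-07). By the 2-fold rule 730 genes rose and 127 fell, 461 of them detected on all 8 arrays, a total within the range for pairs of control slides.

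At day 90, MWCNT lungs still had high Spp1 (6.64, SE 0.55, adjusted p = 8.04e-14), with Reg3b (at least 9.02-fold higher, adjusted p = 1.48e-09), Mmp7 (5.04, SE 0.53, adjusted p = 1.6e-10, detected on 1 of 4 control arrays), and Mt3 (4.66) and Mmp12 (4.65) next. Reg3b encodes a secreted lectin and Mt3 a metallothionein. Of particle- and lipid-handling macrophage genes 13 of 16 rose and 0 fell (13 and 1 adjusted over the list alone, median 1.12 or 0.83 at bounds, adjusted p = 3.33e-15). Of lysosome genes 17 of 20 rose and 0 fell (17 and 0 adjusted over the list alone, median 0.63, adjusted p = 7.73e-18). Complement genes gave 13 of 14 up and 0 down (13 and 0 adjusted over the list alone, median 1.07, adjusted p = 2.79e-18). Among cell cycle genes 9 of 23 rose and 0 fell (12 and 0 adjusted over the list alone, median 0.45, adjusted p = 5.57e-05, adjusted p = 0.411 with an estimated correlation). Top2a (0.41, adjusted p = 0.247), Cdk1 (0.51, adjusted p = 0.145) and Birc5 (0.22, adjusted p = 0.565) did not pass. Mast cell markers were higher, with 4 of 7 up and 0 down (4 and 0 adjusted over the list alone, median 0.94, adjusted p = 0.00434). Of p53 and DNA damage genes 6 of 13 rose and 0 fell (6 and 0 adjusted over the list alone, median 0.12, adjusted p = 0.00933). Among them were Gadd45b (0.61) and Cdkn1a (0.40).

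The lowest values at day 90 were Semg1 (at least 4.26-fold lower, adjusted p = 1.46e-05), Or10s1 (-3.39, detected on 2 of 4 MWCNT arrays), Kcnma1 (at least 5.09-fold lower, adjusted p = 2.92e-06), Lrrc52 (at least 2.69-fold lower, adjusted p = 1.17e-08) and Clca5 (at least 3.24-fold lower, adjusted p = 0.00454). Clock genes gave 8 of 11 up and 3 down (8 and 3 adjusted over the list alone, median 1.73, adjusted p = 1.74e-08). Of B and plasma cell markers 0 of 10 rose and 4 fell (1 and 5 adjusted over the list alone, median -0.50, adjusted p = 0.032, adjusted p = 0.316 with an estimated correlation). Cd79b (-0.92) and Cd79a (-0.76) were lowest. At this day 572 genes rose and 413 fell, 494 of them detected on all 8 arrays. Quantile normalization gave 674 higher and 276 lower, and no filter on dim probes turned the balance to 673 and 4894.

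**Figure D2:**
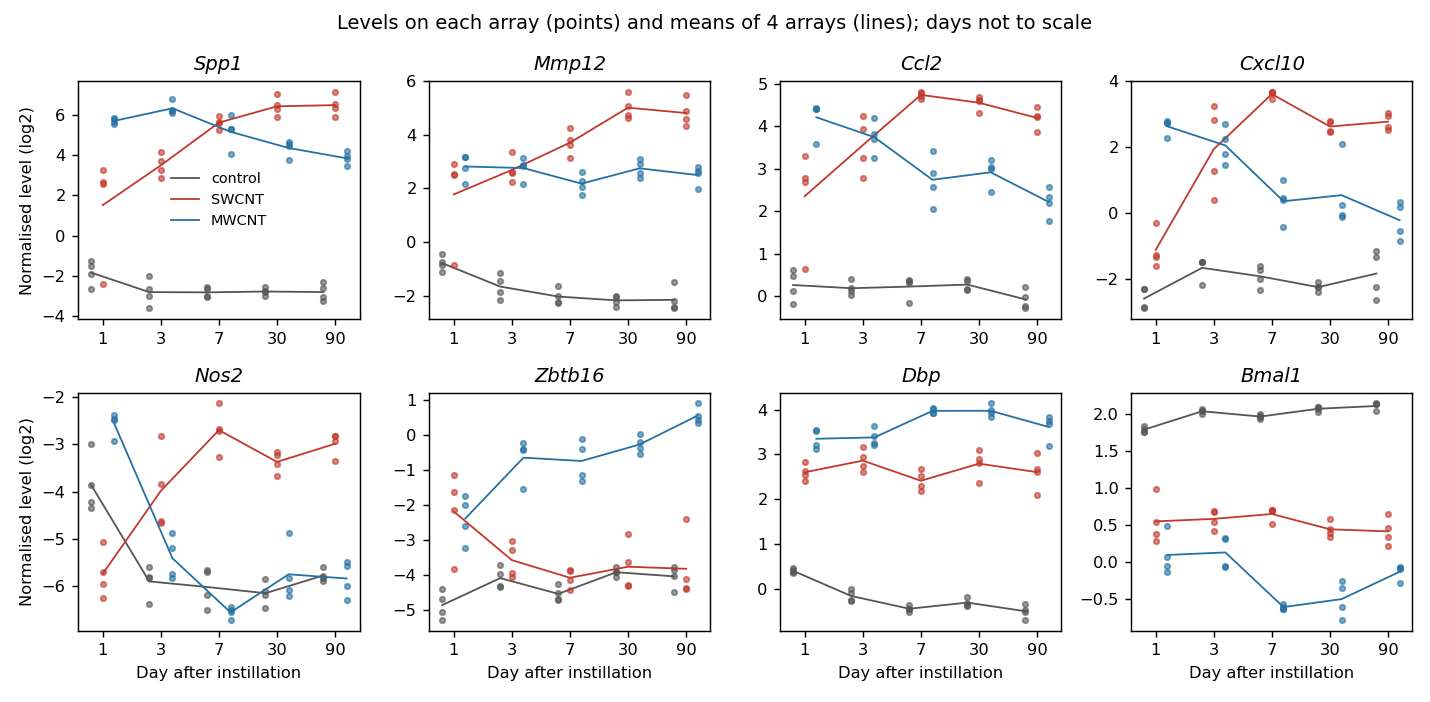
Scaled log2 level of 8 genes on each of the 60 arrays by day and group, with group means, n = 4 arrays each. Spp1 and Mmp12 lie above control in both materials at days 3 to 90, Cxcl10 and Nos2 lie higher in SWCNT than in MWCNT from day 7, and Zbtb16 and Dbp lie higher in MWCNT at days 3 to 90.

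Between materials at day 3, MWCNT lungs held more lysosome transcripts and fewer neutrophil and cholesterol synthesis ones. The genes highest in MWCNT were Apoc1 (3.63, SE 0.25, adjusted p = 5.57e-16), Trh (at least 4.83-fold higher, adjusted p = 3.27e-11), Il24 (3.26), Zbtb16 (2.92, SE 0.38, adjusted p = 2.24e-08) and Spp1 (2.83). Zbtb16 (NM_001013181, probe on chromosome 8 from 51934505 to 51934564) encodes a zinc finger repressor. Of lysosome genes 17 of 20 were higher and 0 lower (17 and 0 adjusted over the list alone, median 0.48, adjusted p = 2.8e-08, adjusted p = 0.101 with an estimated correlation). Neutrophil markers were lower in MWCNT, with 1 of 9 higher and 7 lower (1 and 7 adjusted over the list alone, median -1.09, adjusted p = 0.00404, adjusted p = 0.144 with an estimated correlation). Cxcr2 (-1.77, detected on 2 of 4 MWCNT arrays) and S100a8 (-1.44) were lowest. Of cholesterol synthesis genes 0 of 13 were higher and 9 lower (0 and 9 adjusted over the list alone, median -0.55, adjusted p = 0.000177, adjusted p = 0.256 with an estimated correlation). Interferon-inducible genes hardly parted the materials, with 1 of 16 higher and 1 lower (1 and 1 adjusted over the list alone, median 0.05, adjusted p = 0.833). Cxcl9 (1.29) was higher. The lowest named genes were Ifna4 (-2.95, SE 0.36, adjusted p = 5.2e-09, detected on 3 of 4 MWCNT arrays), Ank2 (-2.11, detected on 2 of 4 MWCNT arrays), Adra1a (at least 1.01-fold lower, adjusted p = 1.89e-07), Col6a6 (at least 3.23-fold lower, adjusted p = 5.25e-09) and Ffar2 (at least 1.14-fold lower, adjusted p = 3.66e-06). In MWCNT 557 genes were higher and 801 lower, 506 of them detected on all 8 arrays. Of those, 322 were higher and 184 lower, and normexp background with 203 and 59 and no filter on dim probes with 1396 and 934 turned the balance too.

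At day 7, interferon-inducible, T cell and neutrophil transcripts were lower in MWCNT than in SWCNT lungs. Of interferon-inducible genes 0 of 16 were higher and 13 lower (0 and 13 adjusted over the list alone, median -1.98, adjusted p = 1.98e-23). Cxcl11 (-3.89), Cxcl10 (-3.25) and Ifit3 (-2.72) were lowest. Of T cell markers 0 of 12 were higher and 10 lower (0 and 11 adjusted over the list alone, median -0.78, adjusted p = 8.11e-13). Icos (-1.21) and Cd2 (-0.97) were lowest. Of neutrophil markers 0 of 9 were higher and 6 lower (0 and 7 adjusted over the list alone, median -0.97, adjusted p = 3.95e-07). S100a9 (-2.91) and S100a8 (-2.18) were lowest. Inflammatory mediators were lower, with 0 of 15 higher and 8 lower (0 and 9 adjusted over the list alone, median -0.53, adjusted p = 4.75e-08). Among them were Nos2 (at least 4.86-fold lower, adjusted p = 1.52e-13). Lymphoid chemokines and receptors gave 0 of 6 higher and 3 lower (0 and 3 adjusted over the list alone, median -0.30, adjusted p = 0.00477). Cxcl13 (-1.76) was lowest. The largest single differences were Gsg1 (-4.18, SE 0.40, adjusted p = 3.48e-11, detected on 3 of 4 MWCNT arrays), Acod1 (at least 7.76-fold lower, adjusted p = 1.05e-09), Orm1 (-4.00, SE 0.44, adjusted p = 1.66e-09, detected on 1 of 4 MWCNT arrays) and Hal (-3.97, SE 0.41, adjusted p = 2.64e-10, detected on 1 of 4 MWCNT arrays) downward. Acod1 makes itaconate and Hal breaks down histidine.

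Upward at day 7 the largest were Zbtb16 (3.33, SE 0.38, adjusted p = 2.86e-09), Dnah3 (at least 2.43-fold higher, adjusted p = 4.88e-05), Trh (1.90, detected on 1 of 4 SWCNT arrays), Wnt10a (at least 1.87-fold higher, adjusted p = 0.00011) and Crisp3 (at least 1.15-fold higher, adjusted p = 0.00933). Wnt10a and Crisp3 turned sign under normexp background, to -0.25 and -0.28. Of clock genes 6 of 11 were higher and 2 lower (6 and 2 adjusted over the list alone, median 0.64, adjusted p = 0.00769), with Dbp (1.56) higher and Bmal1 (-1.26) lower. In MWCNT 144 genes were higher and 229 lower, a total within the range for control pairs. On all 8 arrays 44 and 160 were detected, and normexp gave 20 and 178.

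At day 30, lysosome and particle-handling genes were lower in MWCNT than in SWCNT lungs. Of lysosome genes 0 of 20 were higher and 19 lower (0 and 19 adjusted over the list alone, median -0.77, adjusted p = 6.85e-16). Atp6v0d2 (-2.15) and Ctsk (-1.85) were lowest. Of particle- and lipid-handling macrophage genes 1 of 16 were higher and 12 lower (1 and 12 adjusted over the list alone, median -1.11, adjusted p = 2.17e-09). The largest differences downward were Psca (at least 13.1-fold lower, adjusted p = 5.62e-14), Mmp7 (-3.65, SE 0.53, adjusted p = 3.05e-07), Apoc1 (-3.54, SE 0.25, adjusted p = 9.84e-16), Sctr (-3.12, detected on 3 of 4 MWCNT arrays) and Ccl12 (-3.11). Upward the largest were Zbtb16 (3.49, SE 0.38, adjusted p = 1.93e-10), Kcns2 (at least 2.49-fold higher, adjusted p = 1.01e-05), Efnb1 (2.46, detected on 1 of 4 SWCNT arrays), Gnai1 (at least 1.84-fold higher, adjusted p = 1.81e-07) and Arhgef4 (2.35, detected on 1 of 4 SWCNT arrays). Of alveolar type 1 markers 8 of 9 were higher and 0 lower (9 and 0 adjusted over the list alone, median 0.58, adjusted p = 0.000102, adjusted p = 0.101 with an estimated correlation). In MWCNT 761 genes were higher and 468 lower, 600 of them detected on all 8 arrays. Of those, 214 were higher and 386 lower, and normexp background turned the balance too, to 93 and 301. Both slides of day 30 were scanned on 1 day.

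At day 90, lysosome transcripts were lower and alveolar type 1 markers higher in MWCNT. Of lysosome genes 0 of 20 were higher and 20 lower (0 and 20 adjusted over the list alone, median -0.84, adjusted p = 4.03e-15). Of interferon-inducible genes 0 of 16 were higher and 13 lower (0 and 13 adjusted over the list alone, median -1.51, adjusted p = 5.56e-07, adjusted p = 0.228 with an estimated correlation). Of T cell markers 0 of 12 were higher and 10 lower (0 and 10 adjusted over the list alone, median -0.45, adjusted p = 0.000249, adjusted p = 0.0802 with an estimated correlation). Alveolar type 1 markers were higher in MWCNT, with 9 of 9 higher and 0 lower (9 and 0 adjusted over the list alone, median 0.67, adjusted p = 9.82e-07). Extracellular matrix genes were lower, with 2 of 20 higher and 10 lower (2 and 11 adjusted over the list alone, median -0.33, adjusted p = 0.0153, adjusted p = 0.267 with an estimated correlation), with Col1a1 (-0.83) and Tgfb1 (-0.93) lower and Ccn2 (0.90) higher. The lowest named genes were Hal (-4.13, SE 0.41, adjusted p = 2.26e-11, detected on 1 of 4 MWCNT arrays), Psca (-4.11, SE 0.40, adjusted p = 1.05e-11, detected on 3 of 4 MWCNT arrays), Acod1 (-3.80, SE 0.45, adjusted p = 2.22e-09, detected on 1 of 4 MWCNT arrays), Lrrc52 (at least 4.49-fold lower, adjusted p = 2.84e-11) and Gsg1 (-3.72). The highest were Zbtb16 (4.37, SE 0.38, adjusted p = 3.97e-13), Reg3a (at least 5.46-fold higher, adjusted p = 6.11e-06), Spetex2f (at least 2.23-fold higher, adjusted p = 3.91e-06), Cela3b (at least 1.86-fold higher, adjusted p = 1.05e-07) and Prl8a9 (at least 1.63-fold higher, adjusted p = 7.94e-06). In MWCNT 703 genes were higher and 803 lower, 812 of them detected on all 8 arrays. Quantile normalization turned the balance to 852 and 661. These slides too shared 1 scan day, and the value within it is 1506.

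With the 4 slides of each material at days 3 to 90 as the units, a comparison chosen after seeing the data, the spread between slides enters the error. SWCNT slides had higher Spp1 (8.30, SE 0.60, adjusted p = 3.8e-06) and Mmp7 (at least 149-fold higher, adjusted p = 2.29e-05), then Cxcl11 (at least 33.1-fold higher, adjusted p = 2.4e-05), Mmp12 (6.06), Retnla (5.76), Ccl12 (5.57), Slc26a4 (5.45) and Cxcl10 (4.65). Bounds are given where a slide had 0 of 4 arrays above background. Of cell cycle genes 21 of 23 rose and 0 fell (22 and 0 adjusted over the list alone, median 1.39, adjusted p = 2.56e-16). Of complement genes 12 of 14 rose and 0 fell (13 and 0 adjusted over the list alone, median 1.36, adjusted p = 2.04e-11). Of acute phase genes 11 of 11 rose and 0 fell (11 and 0 adjusted over the list alone, median 1.09, adjusted p = 2.04e-11). Of interferon-inducible genes 14 of 16 rose and 0 fell (14 and 0 adjusted over the list alone, median 1.74, adjusted p = 1.17e-11). Decreases were led by Tac1 (-2.54, SE 0.20, adjusted p = 6.84e-06) and Serpinb10 (-2.22, SE 0.23, adjusted p = 5.69e-05), then Fam124b (at least 3.06-fold lower, adjusted p = 1.17e-05), Inmt (-1.81) and Fmo2 (-1.76). Of endothelial markers 0 of 12 rose and 10 fell (0 and 10 adjusted over the list alone, median -0.78, adjusted p = 2.13e-05, adjusted p = 0.123 with an estimated correlation). Of alveolar type 1 markers 0 of 9 rose and 8 fell (0 and 8 adjusted over the list alone, median -0.51, adjusted p = 6.47e-05, adjusted p = 0.0862 with an estimated correlation). Immediate early genes gave 3 of 9 up and 3 down (3 and 4 adjusted over the list alone, median -0.39, adjusted p = 0.926), and their mean of 0.13 and the test's direction were upward against a negative median. In all 956 genes rose and 340 fell.

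MWCNT slides against control slides gave Spp1 (7.72, SE 0.60, adjusted p = 8.24e-06) and Mmp7 (at least 51.4-fold higher, adjusted p = 0.000226), then Retnla (5.22), Il24 (at least 18.8-fold higher, adjusted p = 0.000237), Dbp (4.08) and Zbtb16 (3.87). Of complement genes 13 of 14 rose and 0 fell (13 and 0 adjusted over the list alone, median 0.98, adjusted p = 2.21e-15). Of MHC class II genes 7 of 7 rose and 0 fell (7 and 0 adjusted over the list alone, median 0.89, adjusted p = 2.55e-11). Of cell cycle genes 21 of 23 rose and 0 fell (21 and 0 adjusted over the list alone, median 0.99, adjusted p = 4.39e-19). Of CC chemokines 8 of 13 rose and 0 fell (8 and 1 adjusted over the list alone, median 1.55, adjusted p = 1.82e-06). The lowest were Bmal1 (-2.32, SE 0.14, adjusted p = 5.37e-07) and Npas2 (-2.24, SE 0.15, adjusted p = 2.75e-06), then Spon2 (-2.00) and Scd (-1.97). Clock genes gave 7 of 11 up and 2 down (8 and 3 adjusted over the list alone, median 1.77, adjusted p = 1.2e-05). B and plasma cell markers fell, with 0 of 10 up and 5 down (0 and 5 adjusted over the list alone, median -0.37, adjusted p = 0.0149). Cd79b (-0.89) was lowest. In all 400 genes rose and 98 fell.

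Between MWCNT and SWCNT slides, 34 genes were higher and 49 lower in MWCNT. The highest included Zbtb16 (3.53, SE 0.25, adjusted p = 1.25e-05) and Fkbp5 (1.63, SE 0.14, adjusted p = 6.63e-05), then Fmo2 (1.26). The lowest included Nos2 (at least 3.83-fold lower, adjusted p = 0.000936) and Ccl12 (-2.62, SE 0.51, adjusted p = 0.0241), then Gsg1 (-2.62), Acod1 (at least 4.2-fold lower, adjusted p = 0.0379), Cxcl10 (-2.05), S100a9 (-1.95) and S100a8 (-1.76). Fkbp5 encodes a co-chaperone of steroid receptors. Of interferon-inducible genes 0 of 16 were higher and 7 lower (0 and 13 adjusted over the list alone, median -1.18, adjusted p = 4.46e-13). Of neutrophil markers 0 of 9 were higher and 4 lower (0 and 7 adjusted over the list alone, median -0.77, adjusted p = 1.82e-07). Alveolar type 1 markers were higher in MWCNT, with 1 of 9 higher and 0 lower (5 and 0 adjusted over the list alone, median 0.35, adjusted p = 9.99e-06). Leaving out 1 slide moved the total of 83 by over 1.5 times for 4 of 8 slides, to 254 without SWCNT day 3, 180 without MWCNT day 3, 53 without SWCNT day 90 and 55 without MWCNT day 7, and adding day 1 gave 13 higher and 4 lower.

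**Figure D3:**
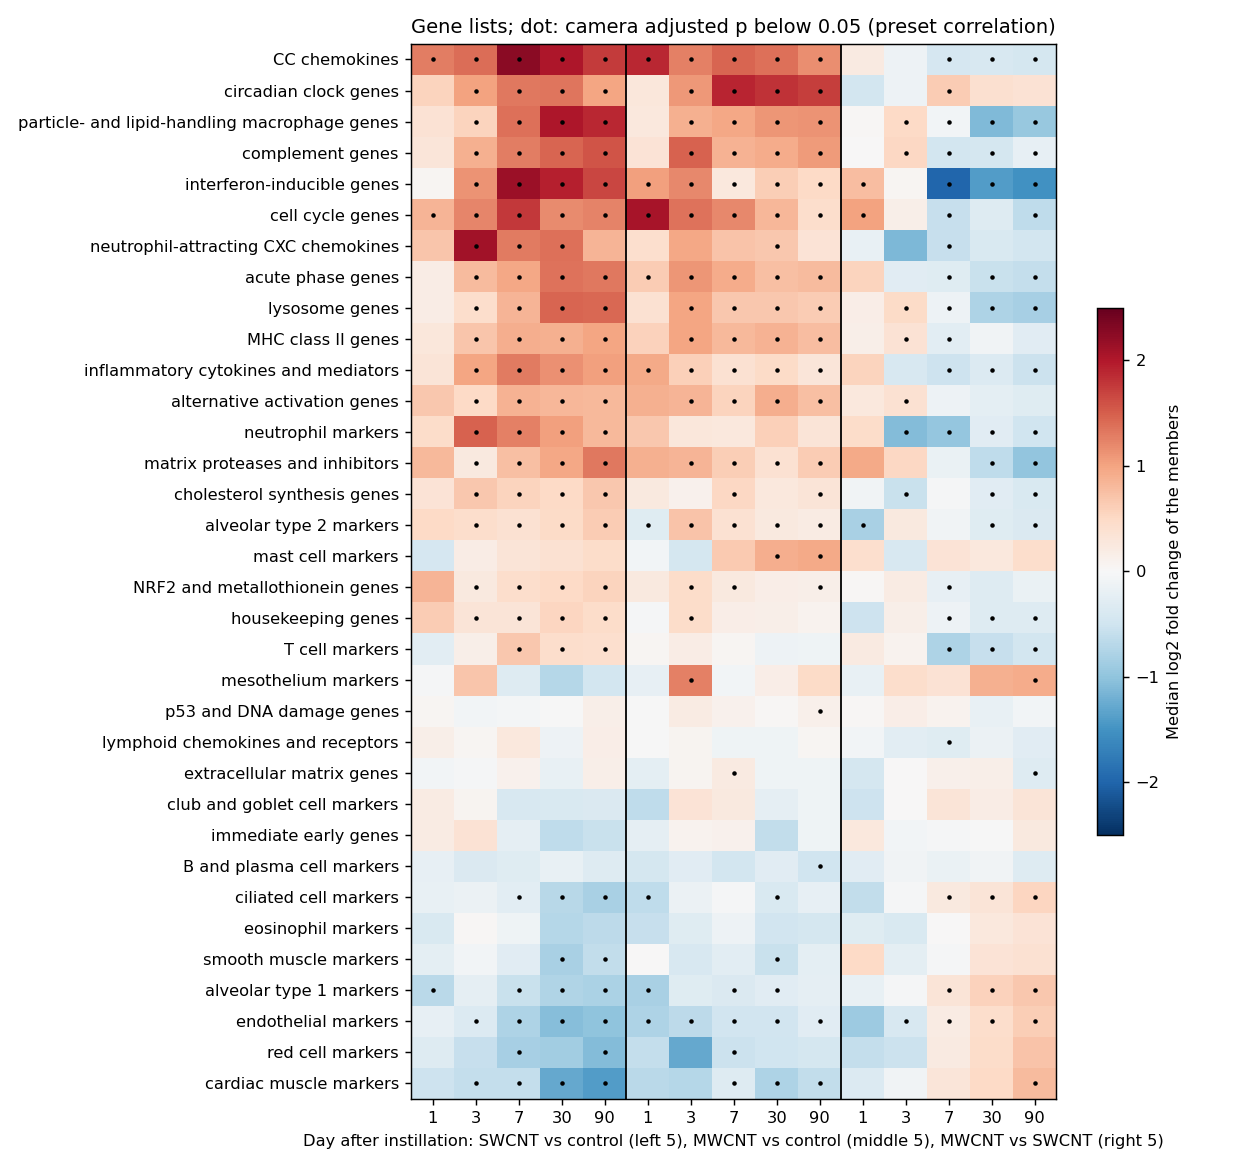
Median log2 fold change of each of the 34 gene lists in the 15 comparisons of a day, with a dot where camera with a preset correlation gave adjusted p under 0.05. Of 510 tests 247 have a dot, 164 upward and 83 downward, and 94 passed with an estimated correlation.

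Over the 15 comparisons of a day, 247 of 510 list tests passed with the preset correlation and 94 with an estimated one, and list calls printed without an estimated value held with it. For the 3 comparisons of slides the counts were 71 and 31 of 102. With members below background set to their bound, 1 of 510 medians changed sign, that of lymphoid chemokines and receptors in MWCNT at day 30, from -0.1 to 0.04, where the test did not pass. Eosinophil markers passed in 0 of 15 comparisons of a day, as did club and goblet cell markers and immediate early genes. The 8 housekeeping genes were not flat, with 6 of 8 up and 1 down (6 and 1 adjusted over the list alone, median 0.54, adjusted p = 0.00326, adjusted p = 0.255 with an estimated correlation) in SWCNT at day 30, with Gapdh (1.11) up and Tbp (-0.17) down.

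At day 1, the comparisons with the control slide of the same day called many genes that separated that slide from the later controls. Against it, SWCNT lungs had Foxe1 (7.32, SE 0.19, adjusted p = 2.05e-35), Rab15 (6.12, SE 0.34, adjusted p = 8.96e-22), Il24 (5.07, detected on 1 of 4 control arrays), Cck (4.51) and Orm1 (4.50) highest. The lowest were Adam26a (at least 3.56-fold lower, adjusted p = 1.76e-09), Or8b1b (at least 2.83-fold lower, adjusted p = 5.98e-08), Gja6 (at least 3.63-fold lower, adjusted p = 1.95e-11), Or10s1 (at least 2.42-fold lower, adjusted p = 0.00016) and Or11h23b (-3.05, detected on 1 of 4 SWCNT arrays). Against the mean of the controls of days 3 to 90, chosen after seeing the data, Foxe1, Rab15 and Cck changed by 0.47, 0.75 and 0.59, while Orm1 (at least 97.5-fold higher, adjusted p = 4.06e-23), Il24 (at least 29.5-fold higher, adjusted p = 4e-18) and Retnla (4.87, SE 0.35, adjusted p = 1.19e-15) were high. Against the later controls, of cell cycle genes 23 of 23 rose and 0 fell (23 and 0 adjusted over the list alone, median 1.97, adjusted p = 6.02e-21, adjusted p = 0.0941 with an estimated correlation). Of CC chemokines 10 of 13 rose and 2 fell (10 and 2 adjusted over the list alone, median 1.69, adjusted p = 4.68e-05, adjusted p = 0.0941 with an estimated correlation). Of complement genes 12 of 14 rose and 0 fell (12 and 0 adjusted over the list alone, median 0.60, adjusted p = 4.02e-05, adjusted p = 0.164 with an estimated correlation). Alveolar type 1 markers gave 0 of 9 up and 8 down (0 and 8 adjusted over the list alone, median -0.36, adjusted p = 0.000705, adjusted p = 0.214 with an estimated correlation). Interferon-inducible genes gave 5 of 16 up and 1 down (5 and 0 adjusted over the list alone, median 0.06, adjusted p = 0.884) against the control of the day, with Cxcl10 up by 1.47.

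In SWCNT at day 1, 3776 genes rose and 1724 fell against the control of the day, or 3304 and 2506 after quantile normalization, which moved the median of all genes from 0.06 to -0.05. Against the later controls the total was 1038, and 1510 without array 1, on which Spp1 was far below the other 3. Without that array Spp1 rose by 4.66 instead of 3.35, Mmp7 by 4.08 instead of 2.96 and Retnla by 4.99 instead of 4.06.

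MWCNT lungs at day 1 had Spp1 (7.54, SE 0.55, adjusted p = 1.73e-17), Il24 (7.38, SE 0.43, adjusted p = 6.39e-21, detected on 1 of 4 control arrays), Orm1 (5.57, SE 0.44, adjusted p = 5.74e-16), Cxcl11 (at least 18.3-fold higher, adjusted p = 1.31e-14) and Rchy1 (at least 14.1-fold higher, adjusted p = 2.82e-16) highest against the control of the day. In contrast, Cdc42ep3 (-5.58, SE 0.24, adjusted p = 3.27e-26), Efhd1 (-5.14, detected on 2 of 4 MWCNT arrays), Car5b (-5.06, detected on 2 of 4 MWCNT arrays), Zfp608 (-5.02) and Npas2 (-4.99, detected on 3 of 4 MWCNT arrays) were lowest. Against the later controls, Orm1 (at least 205-fold higher, adjusted p = 3.19e-28), Spp1 (8.50, SE 0.43, adjusted p = 2.65e-24) and Il24 (at least 146-fold higher, adjusted p = 5.1e-27) were again high, with Cxcl10 (4.54), Ccl22 (4.28) and Ccl2 (4.06). Of cell cycle genes 23 of 23 rose and 0 fell (23 and 0 adjusted over the list alone, median 2.86, adjusted p = 5.18e-09, adjusted p = 0.283 with an estimated correlation) against the later controls. Of acute phase genes 10 of 11 rose and 0 fell (10 and 0 adjusted over the list alone, median 0.96, adjusted p = 0.00243, adjusted p = 0.258 with an estimated correlation). Alveolar type 2 markers were lower, with 0 of 12 up and 9 down (0 and 9 adjusted over the list alone, median -0.58, adjusted p = 0.0219, adjusted p = 0.374 with an estimated correlation). Scd fell by 4.31. The totals were 3485 higher and 2712 lower against the control of the day, and 4338 and 4546 against the later controls.

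Between materials at day 1, 3464 genes were higher and 4470 lower in MWCNT, or 2282 and 2176 among those detected on all 8 arrays. The highest were Or10s1 (at least 13.5-fold higher, adjusted p = 1.09e-09), Gja6 (at least 13.9-fold higher, adjusted p = 2.25e-18), Tmc2 (at least 23.1-fold higher, adjusted p = 1.44e-11), Vom2r73 (at least 13.6-fold higher, adjusted p = 2.87e-13) and Vom2r10 (at least 13-fold higher, adjusted p = 1.08e-14), which include receptors of the nose. The lowest were Rab15 (-8.21, SE 0.34, adjusted p = 1.27e-27), Foxe1 (-7.22, SE 0.19, adjusted p = 2e-35), Cdc42ep3 (-6.65), Zfp608 (-6.14) and Sf3b5 (-5.69). Among cell cycle genes 20 of 23 were higher and 1 lower (20 and 1 adjusted over the list alone, median 1.00, adjusted p = 0.00194, adjusted p = 0.515 with an estimated correlation). Of interferon-inducible genes 10 of 16 were higher and 1 lower (10 and 1 adjusted over the list alone, median 0.78, adjusted p = 0.0438, adjusted p = 0.619 with an estimated correlation). Of alveolar type 2 markers 0 of 12 were higher and 10 lower (0 and 10 adjusted over the list alone, median -0.81, adjusted p = 0.00179, adjusted p = 0.167 with an estimated correlation). Acute phase genes gave 7 of 11 higher and 0 lower (7 and 0 adjusted over the list alone, median 0.55, adjusted p = 0.0609). Lcn2 (1.33) and Lbp (1.44) were higher.

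The effect of SWCNT at day 90 minus that at day 1, tested as a difference of differences, was among the largest for Spp1 (5.93, SE 0.77, adjusted p = 4.43e-09), Mmp7 (5.47, SE 0.76, adjusted p = 1.97e-08) and Csap1 (5.45). It was lowest for Foxe1 (-6.73, SE 0.26, adjusted p = 2.25e-26), Rab15 (-5.67), Slc24a5 (-4.46), Etv3 (-4.36) and Cck (-4.14). Foxe1, Rab15, Cck and Slc24a5 were also the genes by which control lungs rose most from day 1 to day 90, namely Foxe1 (7.00), Rab15 (5.39), Cck (4.37), Slc24a5 (4.15) and Gdnf (3.81). Csap1 (-4.17, detected on 1 of 4 control arrays), Clca1 (-3.94), Reg3b (at least 2.61-fold lower, adjusted p = 1.56e-06), Vch (at least 2.18-fold lower, adjusted p = 1.34e-05) and Tcf21 (-3.23) fell most. This test called 1968 genes upward and 3815 downward, and its median over all genes was -0.15, or -0.04 after quantile normalization. For MWCNT the difference was largest for Cdc42ep3 (5.65), Csap1 (5.35), Car5b (4.82), Rnf111 (4.73) and Prcp (4.69) and among the lowest for Or10s1 (-5.87) and Rnase11 (-5.72), with 2770 upward and 3608 downward. Control day 90 against control day 1 called 3246 upward and 1557 downward.

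Day 90 minus day 3, added after seeing the data, leaves the day 1 slides out. For SWCNT the effect grew for Mt3 (5.26, SE 0.52, adjusted p = 7.63e-11), Apoc1 (4.02), Spp1 (2.99) and Ctsk (3.61), and fell for Wfdc18 (-2.49), Fbll1 (-2.45), Or5b123b (-2.25) and Gpm6a (-2.18). Psca and Sctr also grew, with no size given here or from day 1, as 3 of 4 groups were below background on 4 of 4 arrays. For MWCNT each of the 10 named genes had at least 1 group below background on 4 of 4 arrays, so no size is given. They were Prl8a9, Spetex2f, Stfa3, Tyr and Ankrd34b upward and Semg1, Hal, Clca5, Tecta and Acod1 downward. Spp1 fell by 2.49 (adjusted p = 0.0101). The totals were 783 upward and 339 downward for SWCNT and 1379 upward and 761 downward for MWCNT, where normexp background with 264 and 412 and no filter on dim probes with 1586 and 4800 turned the balance.

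At all 5 days, 53 genes were at least 2-fold higher in both materials and 9 lower. The 10 with the highest mean change were Spp1, Mmp7, Retnla, Mmp12, Il24, Atp6v0d2, Cxcl11, Slc26a4, Ccl12 and Gsg1. The 10 lowest in either material were Scd, Npas2, Tac1, Spon2, Bmal1, Serpinb10, Fam124b, Arsi, Gnat2 and Cyp4b1. SWCNT alone gave 162 higher and 19 lower genes at all 5 days, and MWCNT alone 120 and 21. At days 3 to 90, 348 genes were higher in SWCNT, 200 in MWCNT and 131 in both.

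Both materials were compared with 1 set of controls per day, which by itself makes their changes alike. At days 3, 7, 30 and 90, 411, 513, 487 and 347 genes rose at least 2-fold in both, and 458, 98, 109 and 144 fell. Independent draws would share 24.2, 31, 46.7 and 33.3 of the higher genes. With the 4 controls split between the materials, 370.3, 436, 428.8 and 315.7 higher genes were shared. The covariance of the changes was 0.25, 0.196, 0.237 and 0.206, against 0.0207 to 0.021 from simulated array noise of shared controls. Both tests leave a control slide effect open. At day 1 the values were 1036 shared higher genes, 534 by independence and 982.5 with split controls, and 742 genes moved in opposite directions.

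**Figure D4:**
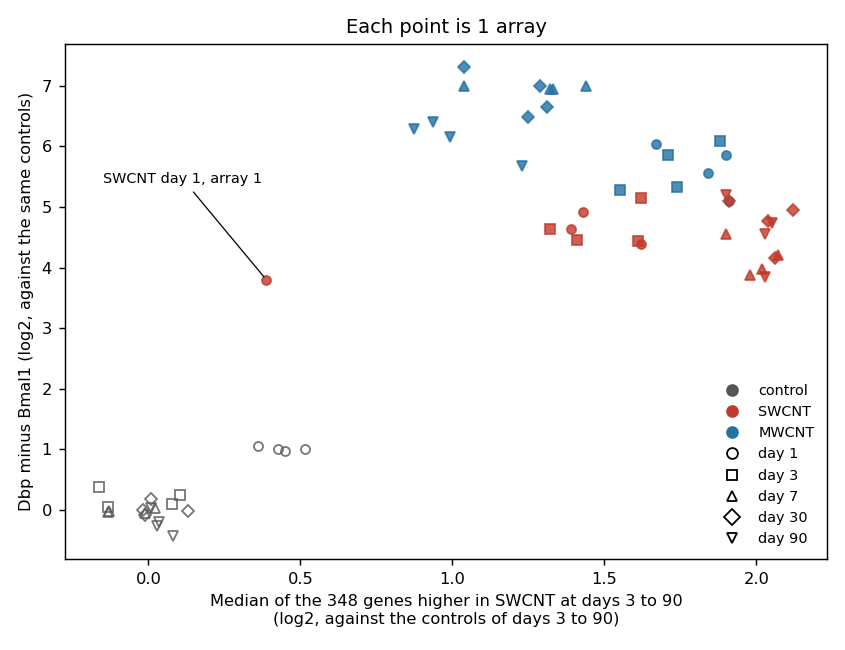
Dbp minus Bmal1 (log2, relative to later controls) against the median of the 348 genes higher in SWCNT at days 3 to 90, 1 point per array. The 12 MWCNT arrays of days 7 to 90 lie at a clock shift of 5.67 to 7.3 and a response of 0.874 to 1.44, the 12 SWCNT arrays at 3.84 to 5.2 and 1.9 to 2.12, and the 20 control arrays at -0.425 to 1.05.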

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

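The tests of other splits were planned for the comparisons of a day and for day 90 against day 1, while those of slides and of day 90 minus day 3, and all tests of the 3 patterns weighed here, were chosen after the result was seen.

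In SWCNT lungs at day 1, array 1 lay far from the other 3 in 6 genes that nanotubes raised, with levels (log2 relative to the 75th percentile) of -2.43 for Spp1, -4.30 for Mmp7, 0.50 for Retnla, -0.86 for Mmp12, -3.14 for Atp6v0d2 and -4.22 for Gsg1. Cxcl11 was apart on array 3 of MWCNT day 30 at -1.19, and Retnla on array 1 of MWCNT day 90 at 3.03. Of spots, 62.3% were well above background on array 4 of control day 1. Chance marks about 1 in 20 groups, and 180 tests marked 9, where 9 were expected.

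The genes responding on the later slides were weak on array 1 of SWCNT day 1. Over the 348 genes higher in SWCNT at days 3 to 90, its median was 0.388 above the later controls, against 1.39 to 1.62 on the other 3 arrays and 0.36 to 0.514 on the day 1 controls. Its 71.6% of spots well above background cannot exclude a poor array, as MWCNT day 1, also apart, reached 71.7%. Its Dbp minus Bmal1 shift of 3.80 (others 4.39 to 4.92, 20 control arrays at most 1.05) argues against a control rat. A lung with little or no nanotube response may explain it, unless the shift is one, a hypothesis from 1 array.

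Differences between nanotube and control lungs changed between days by a test of the change itself. Day 90 minus day 1 called 5783 genes for SWCNT and 6378 for MWCNT, and day 90 minus day 3 called 1122 and 2140. Those from day 1 carry the control slide of day 1, which alone gave 4803 genes against day 90, so they are not shown to be nanotube effects. For SWCNT, 2 of 100 splits of the arrays called as many genes from day 1 to 90, the real one included, and the highest other called 6970. For MWCNT it was 1 of 100, with 5682 the highest other. From day 3 to 90, 7 of 100 splits called as many for SWCNT, so chance cannot be excluded, and the highest other called 4340, above the real count. For MWCNT it was 3 of 100, with 3784 the highest other, again above the real count. These splits mix nanotube and control arrays within each day. A draw near the real split of a day, or its reverse, thus carries the whole nanotube effect of that day. Hence they cannot decide whether the change between days is chance. A slide effect stays open too, since each change rests on 4 slides.

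Between 2 groups of a day, the real split of 35 called the most genes in each of the 15 comparisons (1 of 35, the least possible), which argues against chance in array spread. SWCNT against control called 5500, 1254, 1481, 2888 and 2727 genes at days 1, 3, 7, 30 and 90, where the highest other split called 2355, 185, 333, 762 and 601. MWCNT against control called 6197, 2995, 838, 857 and 985, against 2805, 725, 205, 32 and 35. MWCNT against SWCNT called 7934, 1358, 373, 1229 and 1506, against 3409, 281, 50, 302 and 370. For control day 90 against day 1 it was 1 of 35 as well, with 4803 and 1359. These splits leave a slide effect open, since each group is a slide. With slides as units, 1296 genes in SWCNT (1 of 35, highest other 184) and 498 in MWCNT (1 of 35, highest other 0) argue against chance, while 83 between materials do not (2 of 35, highest other 141).

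Olfactory receptor genes, foreign to lung, were higher on the control and MWCNT slides of day 1. The median of 222 such genes was 0.874 and 1.41 above the later controls, and 0.122 on the SWCNT slide. The filter on dim probes chose these genes in part on the same slides, and the 170 it kept without day 1 gave 0.649, 1.13 and 0.131. With no filter, 1112 gave only 0.381, 0.576 and 0.0622, and MWCNT day 90 lay further off at -0.911. The deviations of the control and MWCNT slides correlated at 0.609 across genes. If transcript levels had changed, 2 probes of a gene should move together, as they did in nanotube groups of days 3 to 90 with correlations of 0.591 to 0.819 over 2952 genes. On the MWCNT slide the value was 0.352 and on the control slide 0.176, although deviations there were larger (SD 1.23 and 0.785, against at most 0.61), which argues against transcript changes as the whole cause. An early effect of the instillation is argued against by a correlation of only 0.148 between control and SWCNT slides. Loss of 5′ ends stays open as a part of the cause. Of pairs of probes parted at least 2-fold, the 5′ one was lower in 70.4% on the control and 70.8% on the MWCNT slide and higher in the others, which such a loss would not give. A difference in how these slides were labelled or hybridised may remain too, which no value here tests, and a biological response was present beside it, as the 348 genes had a median of 1.77 on the MWCNT slide.

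Clock genes differed between nanotube and control lungs from day 3 to 90. In 8 of 8 groups, the 5 clock genes past the threshold moved in opposite phase, with Bmal1 and Npas2 down and Dbp, Nr1d1 and Per3 up. A shift that follows the size of the tissue response is argued against at days 7 to 90, since the 12 MWCNT arrays had a lowest shift of Dbp minus Bmal1 of 5.67 with a response of 0.874 to 1.44, while the 12 SWCNT arrays had 3.84 to 5.20 with a response of 1.90 to 2.12. These responses are over genes chosen on SWCNT, but the 200 genes higher in MWCNT gave the same order (1.37 to 1.90 in MWCNT and 2.03 to 2.90 in SWCNT). The fixed lists did so too (0.203 to 0.396 and 0.463 to 0.655). At day 3 it stays open, as MWCNT arrays had the larger shift (5.28 to 6.08, against 4.44 to 5.14) and mostly the larger response (1.55 to 1.88, against 1.32 to 1.62). Time of day of tissue sampling and an effect of nanotubes on the clock cannot be told apart, because no label gives the hour.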

How the results depend on the processing

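Under quantile normalization, the mean of all probes of a gene, the authors' per-array values, eBayes without an intensity trend, fits of only the groups compared and, for slides, day as a block, the count of genes of each comparison lay within 1.5 times the reported one. The authors' values gave none for control day 90 against day 1, since they are centred on the controls of each day, and slide as a block could not be fitted, because each slide holds 1 group. Normexp lowered 22 of the 23 counts by more, all but SWCNT at day 7. SWCNT against control fell to 2275, 350, 1403 and 1358 at days 1, 3, 30 and 90, MWCNT to 3039, 968, 345, 305 and 307 over the 5 days, and MWCNT against SWCNT to 4227, 262, 198, 394 and 564. Day 90 minus day 1 gave 2877 and 3431, day 90 minus day 3 gave 445 and 676, the controls 1793, and slides 730, 248 and 52. Its offset of 50 shrinks folds of dim probes by construction. It reversed Wnt10a (-0.25) and Crisp3 (-0.28) in MWCNT against SWCNT at day 7, and there turned the direction of the list tests of MHC class II, housekeeping, lysosome and particle-handling genes, with medians of -0.0514, 0.0322, -0.00727 and 0.092 in place of -0.26, -0.13, -0.12 and -0.07. Quantile normalization turned that of alveolar type 2 markers between materials at day 30, with a median of -0.0478 in place of -0.30. The cause of these turns was not tested.

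With no filter on dim probes, MWCNT against control called 1308 genes at day 30 and 5567 at day 90, MWCNT against SWCNT 2330 at day 3 and 7021 at day 90, and the MWCNT changes from day 1 and day 3 to day 90 were 10060 and 6386. Probes above background on at least 50% of arrays gave 621 for MWCNT at day 90. The cause was not tested for these filters. For dim genes, signal over background limits the fold, which is then only a lower bound. Controls of all 5 days gave 1064 for SWCNT at day 1. Chosen after seeing the data, the controls of days 3 to 90 gave 1038, or 1510 without array 1, and adding day 1 to the slides gave 829 for SWCNT and 17 between materials, where the cause was not tested.

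Leaving out 1 array gave, for SWCNT at days 1, 3, 7, 30 and 90, 5176 to 6182, 1148 to 1352, 1441 to 1610, 2561 to 3310 and 2467 to 3085 genes. For MWCNT the ranges were 5870 to 6661, 2805 to 3161, 754 to 927, 799 to 890 and 943 to 1011, and between materials 7731 to 8205, 1186 to 1460, 333 to 437, 1078 to 1514 and 1288 to 1789. Day 90 minus day 1 gave 5521 to 6047 for SWCNT and 5999 to 6834 for MWCNT, day 90 minus day 3 gave 910 to 1207 and 1963 to 2290, and the controls 4654 to 5066. Leaving out 1 slide gave 996 to 1851 for SWCNT, 360 to 582 for MWCNT and 53 to 254 between materials, where 254 came without SWCNT day 3, 180 without MWCNT day 3, 53 without SWCNT day 90 and 55 without MWCNT day 7.

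Of 510 list tests, 247 passed, 94 did so with an estimated correlation and 403 with fry, which asks whether members move, on balance, 1 way. Quantile normalization left 476 of 510 on their side of the threshold with their direction, normexp 458, no filter 476, the stricter filter 499, the mean of probes 490 and no trend 506. Of 1976 list medians with 1 array left out, 1 changed sign. Of 200 named values, quantile normalization left 199 the same, normexp 162, no filter 198, the mean of probes 200, no trend 198 and only the groups compared 198. The authors' values left 188 of 190, the stricter filter 155 of 155, and leaving out 1 array 1887 of 1920. Apart from the reversals named here, those named values that were not the same became weaker. List tests also became stronger, 13 with quantile normalization, 34 with normexp, 28 with no filter, 14 with the mean of probes and 158 with fry.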

Other observations

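The airway mucin gene Muc5ac rose early in MWCNT lungs, as Muc5ac (2.92, detected on 2 of 4 control arrays) at day 3 and Muc5ac (at least 2.5-fold higher, adjusted p = 7.84e-05) at day 7 passed, while at day 90 its -0.07 did not (adjusted p = 0.94). The secretory cell gene Scgb3a1 changed by -1.35, -1.05 and -0.97 at days 7, 30 and 90 in SWCNT and by -1.03, -1.01, -1.09 and -0.53 at days 3 to 90 in MWCNT. Alox15, a lipoxygenase gene, changed by -1.45, -1.70, -2.08 and -1.46 in SWCNT and by -1.84, -1.58, -1.20 and -0.73 in MWCNT at these 4 days.

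The plasma cell gene Tnfrsf17 rose in SWCNT lungs by 0.76, 1.62 and 1.17 at days 7, 30 and 90 and in MWCNT lungs by 1.01 at day 3, with 0.68, -0.01 and 0.30 later not passing. Elastin transcript, Eln, changed by -0.85, -0.58, -1.04 and -0.67 in SWCNT at days 3 to 90 and by -1.01, -1.44 and -1.28 in MWCNT at days 3, 30 and 90, while Tgfb1 rose by 0.59, 0.98, 1.18 and 1.81 and by 0.53, 0.50, 0.38 and 0.88 in SWCNT and MWCNT at days 3 to 90. Ccn2 changed in MWCNT by 1.05, 0.58, 0.54 and 0.84 at these days, and in SWCNT its -0.09, 0.20, 0.03 and -0.06 did not pass.

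The deposited values of SWCNT day 1 array 3 equal those of control day 1 array 3 to within 5e-05, while the scanner signals of the 2 arrays differ (Pearson correlation 0.953 across probes). No other 2 arrays had deposited values correlating above 0.845. The series table equals the mean of the 4 per-array values in 14 of 15 groups, and for SWCNT at day 1 only 2.84% of probes lie within 0.01 of it.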
